A study of Bos taurus with 6 samples.

How the data were processed

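RNA-seq libraries were made from 6 pools of 7 bovine metaphase II oocytes, 3 matured without and 3 with 1e-09 M melatonin. Per the labels' protocols, oocytes were lysed directly, cDNA was made with SuperScript III, amplified and fragmented, and libraries were sequenced as paired ends of 150 bases. Amplification from so few cells without molecular identifiers means that counts are not independent molecules, and intervals on counts cover counting error only. The genome build was UMD3.1, per the submitters' processing notes. The aligner, the quantifier, the annotation release and the filters are not given in the sources used here.

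Per the file headers, each library's file gives an identifier headed gene_id, a length, an expected count and an FPKM value. The identifiers have the form of Ensembl transcript identifiers, so rows are called transcripts here. Whether a row stands for a transcript or for a gene named by a transcript is not given. The expected counts deposited by the authors are estimates: 12.4% to 13.7% of the listed transcripts in a library had a count that was not whole, as when reads that fit several transcripts are divided among them. Transcripts that share sequence with a near-identical copy are uncertain for that reason. The FPKM values deposited by the authors are scaled to transcript length and to the library's summed expected counts. The FPKM implied effective lengths that were shorter than the listed lengths by a median of 132, 93.0 and 235 bases in control replicates 1, 2 and 3, and by 187, 193 and 112 bases in melatonin replicates 1, 2 and 3. These deductions change the FPKM of short transcripts most. No transcript is listed at 0, the smallest listed FPKM is 0.01, and a transcript absent from a library's file was entered as 0. In each library 18.8% to 20.9% of the listed transcripts had fewer than 5 counts, where counting error is large. The reference table used here matched 0 of 15783 identifiers, so neither gene names nor coordinates are given, and the gene lists fixed before the data were examined were not tested.

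Samples were grouped by their treatment label. Nothing in the labels says that the pools came from separate collections or animals, so p-values measure only the spread between these pools. Chi-square tests of the counts between the libraries of each of the 15 pairs gave 12.3 to 120 per degree of freedom over transcripts with at least 20 counts in the pair, far above counting noise, so no pair was 1 library sequenced again; a second amplification of 1 pool would not be told from this. Both groups carry replicate numbers 1, 2 and 3. No label says that a number marks a shared collection or day, so the fit has no block.

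The main test was limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(FPKM + 1), over transcripts with a mean FPKM of at least 1 over the 6 libraries, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on the log2(FPKM + 1) scale understates the change of low transcripts. The design was fixed for FPKM values before the data were examined. The files proved to hold expected counts as well, so edgeR 4.0.16 (quasi-likelihood test, TMM scaling) and DESeq2 1.42.0 were added as alternatives on the expected counts, rounded to whole numbers, over the same transcripts. Library measures were compared with exact two-sided permutation tests, 6 in the adjusted family; those of alternative cutoffs and scalings are outside it and unadjusted. Both limma and edgeR were tested on simulated data: 5 sets of counts were drawn for the 9055 transcripts with the real means, dispersions and library sizes, with 200 transcripts changed per set, drawn from those with a mean count above 10. In those sets limma called 39 and edgeR called 41 of 44275 unchanged transcripts, and edgeR recovered 9.2% of 2-fold, 66.0% of 4-fold and 93.2% of 8-fold changes. Each transcript was drawn on its own, without a length trend or other structure shared between transcripts. The simulated false calls can therefore understate those in the real libraries.

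Alternatives covered the pseudocount (0.1 and 0.5), the filter (none, 0.1 and 5 FPKM), scaling between libraries (same sum, median of ratios, quantile), the variance model, the replicate block, each library left out in turn, and the threshold. The 4 transcripts described by identifier were chosen by a rule fixed before the data were examined: where fewer than 5 transcripts pass in a direction, those with the smallest unadjusted p are given as values. The rule asked for gene symbols and allowed 10 per direction. Without symbols only a pair per direction is printed.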

Results

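Transcript abundance was measured by RNA-seq in bovine (Holstein) oocytes at metaphase II, the stage at which a mature oocyte waits for fertilization. The oocytes had been matured in vitro without melatonin (control) or with 1e-09 M melatonin. Melatonin is the pineal hormone that is also known as a scavenger of free radicals. Each library was made from a pool of 7 oocytes, with 3 libraries per group. Summed expected counts were 7472853, 7002042 and 7565669 in control replicates 1, 2 and 3, and 7335273, 7285736 and 7087712 in melatonin replicates 1, 2 and 3. Depth differed between the groups by less than the spread between libraries (7346850 ± 302201 in control and 7236240 ± 130992 in melatonin, SD, n = 3; exact permutation test, two-sided, p = 0.60). In total, 15783 transcripts were listed in at least 1 library and 10715 in all 6. The files do not pair the Ensembl transcript identifiers with gene names, and 0 of the 15783 matched the reference table used here, so transcripts are described by identifier and no pathway or cell type marker list was tested.

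The first question was whether the melatonin libraries differed from the controls in how many transcripts were expressed and how abundance was distributed among them. Fewer transcripts reached an FPKM of at least 1 in melatonin oocytes, and the most abundant transcripts took a larger share. The number at FPKM of at least 1 was 9088 ± 227 in control and 8785 ± 78.8 in melatonin (SD, n = 3). All 3 melatonin libraries (8725, 8874 and 8755) lay below all 3 controls (9347, 8922 and 8995). The 10 highest transcripts of each library held 17.5% ± 0.611 of the summed FPKM in control and 21.1% ± 0.834 in melatonin (SD, n = 3). Again the groups did not overlap, with 16.8% to 18.0% in control and 20.3% to 21.9% in melatonin. Summed FPKM was 9.64% higher in melatonin, also without overlap. The mean length of a transcript, weighted by its counts, was 2257 ± 98.4 bases in control and 2158 ± 26.0 bases in melatonin (SD, n = 3).

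With 3 pools against 3, the design cannot reach an exact two-sided permutation p below 0.10, and the number of transcripts at FPKM of at least 1, the share of the 10 highest and the summed FPKM each gave p = 0.10 in that exact test. The weighted length gave an exact p of 0.20 and the number of transcripts listed an exact p of 0.30. After Benjamini-Hochberg adjustment over these 6 library measures, including total counts, the smallest exact permutation p was 0.20. The groups overlapped in the share of the 50 highest transcripts (4.64 percentage points higher in melatonin) and in the number of transcripts at FPKM of at least 0.1 (difference of -267), each with an exact permutation p of 0.20. The number at FPKM of at least 5 differed by -323, with an exact permutation p of 0.10. Without control replicate 1 the difference in transcripts at FPKM of at least 1 shrank from -303 to -174. With libraries scaled by the median of their ratios, which takes out a shift shared by most transcripts, it was -62.0, with an exact permutation p of 0.70.

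**Figure D1:**
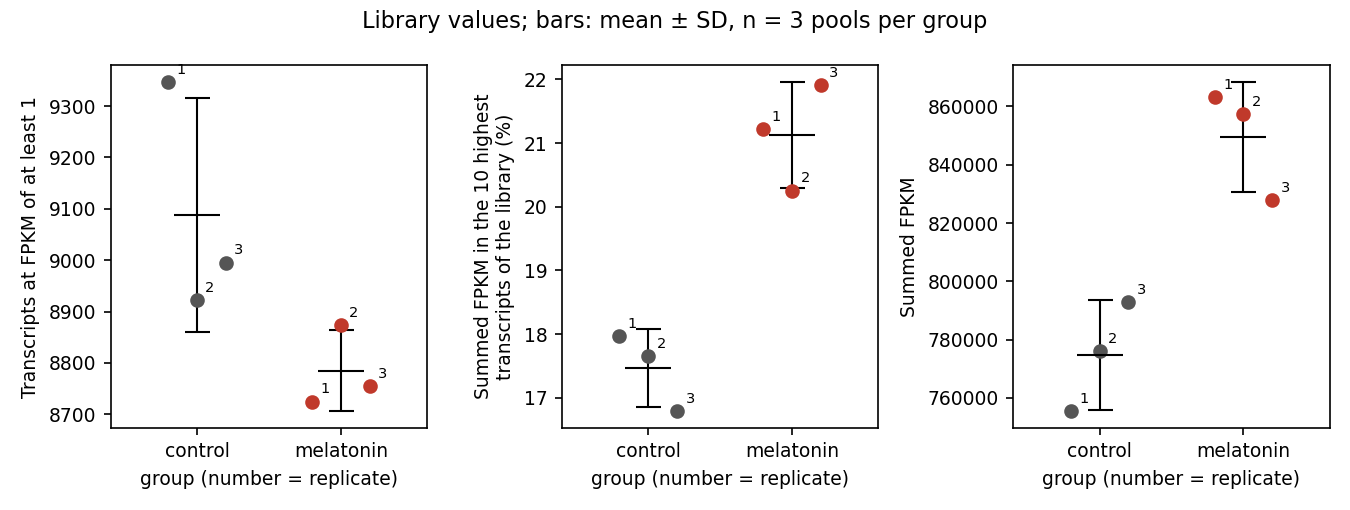
Per-library values in the control and melatonin groups: transcripts at FPKM of at least 1 (left), the percentage of summed FPKM in the 10 highest transcripts (middle) and summed FPKM (right). Points are single libraries with their replicate numbers, bars give the mean ± SD of 3 libraries, the axes do not start at 0, and in each panel the groups did not overlap.

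The second question was whether the libraries of one treatment resembled each other more than they resembled those of the other treatment. No such excess was seen. Across the 9055 transcripts with a mean FPKM of at least 1, the correlation of log2(FPKM + 1) between libraries averaged 0.952 within groups and 0.955 between groups. The difference of -0.0026 was smaller than the SD of 0.0186 among the within-group values. Its sign was not stable: without single libraries it ranged from -0.0096 (without control replicate 1) to 0.0065 (without melatonin replicate 3), and it was 0.0026 without control replicate 2, -0.0076 without control replicate 3 and -0.0044 without melatonin replicate 1. These correlations are across transcripts, which are not independent replicates. The closest pair was melatonin replicates 1 and 2 (r = 0.980), but control replicate 2 correlated with each of them nearly as well (r = 0.977 and 0.978). Melatonin replicate 3 correlated better with control replicate 1 (r = 0.965) than with melatonin replicates 1 and 2 (both r = 0.932). The first principal component held 47.6% of the variance and placed control replicate 1 (-37.6) and melatonin replicate 3 (-42.2) at one end, and melatonin replicates 1 and 2 (33.5 and 32.4) at the other. The second component held 24.2% of the variance, with scores of -18.0, 8.7 and -36.3 in control replicates 1, 2 and 3 and 11.4, 2.6 and 31.6 in melatonin replicates 1, 2 and 3, so that it parted the treatments except for control replicate 2.

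**Figure D2:**
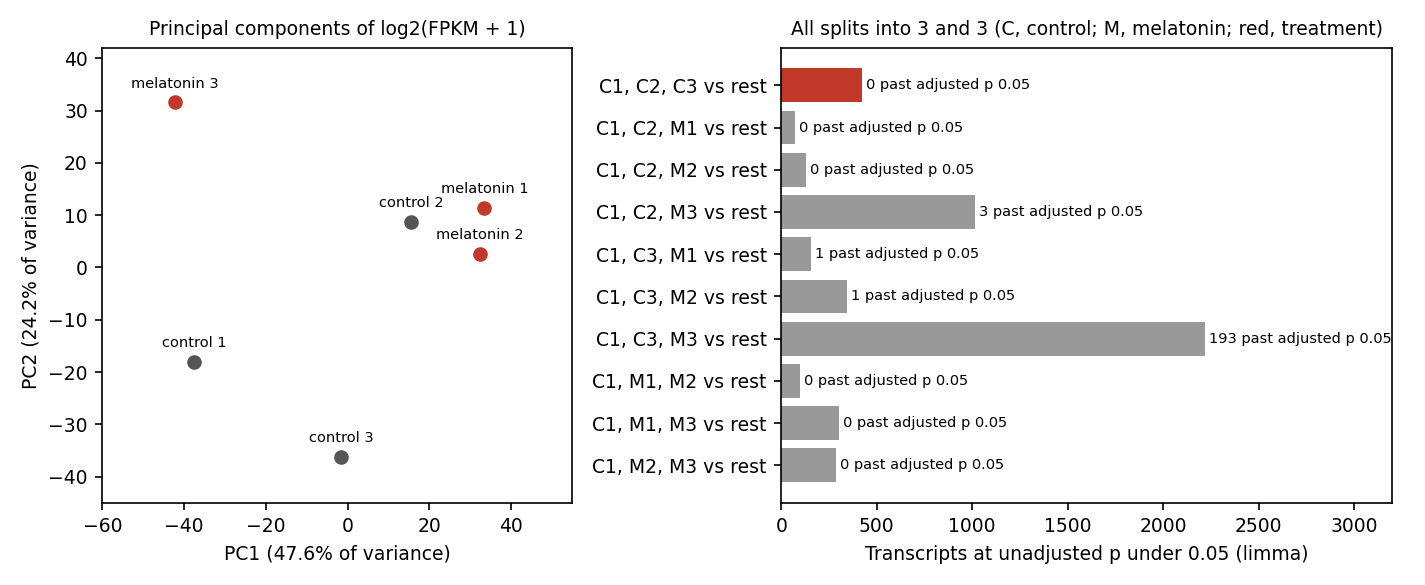
Left, the 6 libraries on the first and second principal components of log2(FPKM + 1), controls in grey and melatonin in red, with the variance each component holds. Right, transcripts at an unadjusted limma p under 0.05 for each of the 10 splits of the 6 libraries into 3 and 3, with the number past an adjusted p of 0.05 beside each bar; the treatment split (red) gave 425 and 0, and the split of control replicates 1 and 3 and melatonin replicate 3 from the rest gave 2221 and 193.

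The main comparison asked which transcripts differed in abundance between melatonin and control oocytes. No transcript passed the test. Of 9055 tested, 0 were higher and 0 were lower with melatonin at an adjusted p below 0.05 in limma, and the smallest adjusted p was 0.945. At an unadjusted limma p under 0.05, 67 transcripts were higher and 358 were lower, together 425. The quasi-likelihood test of edgeR on the expected counts also called 0 transcripts, with 103 higher and 182 lower at an unadjusted p under 0.05. DESeq2 called 2 transcripts higher and 0 lower, with 132 higher and 187 lower at an unadjusted p under 0.05. None of these totals exceeded the share of 0.05 of the tested transcripts that chance gives at this threshold. Some other limma fits of all 6 libraries did exceed it. They gave 734 with libraries scaled to the same sum, 1510 with array weights and 506 with each library's trend with transcript length removed. The remaining fits of all 6 libraries did not. Without control replicates 1, 2 and 3 in turn, 144, 901 and 184 transcripts reached an unadjusted p under 0.05 in limma. Without melatonin replicates 1, 2 and 3 in turn the number was 177, 335 and 959.

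The small differences leaned towards lower values with melatonin, except at high abundance. The median log2 fold change of FPKM + 1 was -0.14 over all tested transcripts. It was -0.17 for the 3058 transcripts with a mean FPKM of 1 to 5, -0.20 for the 2537 at 5 to 20 and -0.13 for the 2239 at 20 to 100. For the 1221 transcripts at 100 or more it was 0.03, and 19 of these were higher and 16 lower at an unadjusted p under 0.05. Of the 9055 transcripts, 762 had all 3 melatonin values below all 3 control values and 144 had them all above. Together these made 10.0% of the transcripts, and chance gives 10%. Of the 425 transcripts at an unadjusted p under 0.05, 84.2% were lower with melatonin. That share was 94.7% with libraries scaled to the same summed FPKM, 43.3% with median-ratio scaling and 53.2% with quantile normalization. The median log2 fold change was 0.03 with median-ratio scaling and in DESeq2, and 0.01 with quantile normalization and in edgeR. All these centre the libraries on each other and so take out a shift shared by most transcripts, whatever its origin. Without melatonin replicate 3 the median was -0.08 and the share lower was 59.9%, and with control 1 and melatonin 3 left out together, the pair at one end of the first component, it was 45.1%.

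**Figure D3:**
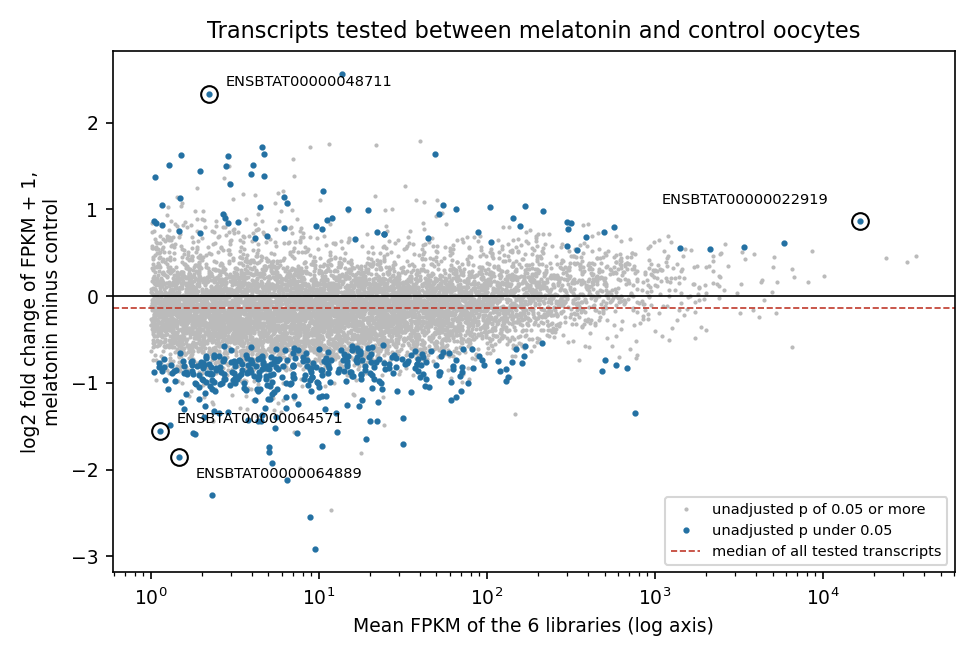
Log2 fold change of FPKM + 1 (melatonin minus control, 3 libraries per group) against the mean FPKM of the 6 libraries on a log axis, 1 point per tested transcript. Blue points are the 425 transcripts at an unadjusted limma p under 0.05, circles mark the 4 transcripts described by identifier, and the dashed line is the median of -0.14.

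The spread between libraries set how large a change these data could show. The median standard error of a log2 fold change was 0.32, and the median half-width of its 95% interval was 0.73. On the log2(FPKM + 1) scale the interval, not corrected for the number of transcripts, lay within 2-fold in either direction for 48.2% of transcripts. It lay within 4-fold for 96.6%. That scale understates the change of low transcripts, so for these such an interval does not exclude a larger fold of FPKM. On the same scale, 41.0% of transcripts at a mean FPKM of 1 to 5 and 54.3% of those at 100 or more had an interval within 2-fold. In counts simulated for this comparison over the same 9055 transcripts, with changes given only to transcripts with a mean count above 10, limma recovered 8.8% of 2-fold, 62.4% of 4-fold and 92.4% of 8-fold changes. Most 2-fold changes were therefore not detectable with this number of libraries and this spread.

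The 2 transcripts with the smallest unadjusted limma p in each direction are given as values, because none passed the test (adjusted p = 0.945 for each in limma). ENSBTAT00000048711 (2423 bases) had FPKM of 4.70, 1.85 and 6.77 in melatonin replicates 1, 2 and 3, and was not listed in any control library. Its log2 fold change of FPKM + 1 was 2.33 ± 0.39 (SE), its adjusted p was 0.721 in edgeR, and it was 1 of the 2 transcripts called by DESeq2 (adjusted p = 3.12e-07). Its expected counts of 77.17, 30.09 and 110.86 were not whole, as when reads that fit several transcripts are divided among them. A transcript with at least 20 counts in each of 3 libraries and unlisted in the other 3 was found for 9 of the 20 possible choices of 3 libraries. ENSBTAT00000022919 (1144 bases) was among the most abundant transcripts, with 11709 ± 1207 FPKM in control and 21306 ± 1747 FPKM in melatonin (SD, n = 3). It held 1.15% of all counts in control and 2.09% in melatonin, a 1.82-fold difference in mean FPKM, and its libraries did not overlap. Its log2 fold change was 0.87 ± 0.21 (SE). It was 0.27 with quantile normalization and 0.73 to 1.07 in every other setting that tested it. Its counts also were not whole.

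The pair with lower values in melatonin rested on few counts. ENSBTAT00000064571 (876 bases) had 17, 7 and 11 counts in the controls and 0, 0 and 1 in the melatonin libraries. Control exceeded melatonin 34.5-fold in summed counts per total, with an exact conditional 95% interval of 5.79 to 1400 that covers counting error only. Its log2 fold change of FPKM + 1 was -1.56 ± 0.32 (SE). ENSBTAT00000064889 (168 bases) had 1 count in each control and was not listed in any melatonin library, so no fold is given. Its fitted log2 fold change of -1.85 ± 0.38 (SE) came from FPKM of 1.88, 1.61 and 5.25, which a single count gives on so short a transcript. Its adjusted p was 0.998 in edgeR, as was that of ENSBTAT00000064571.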

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

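Of 25 other ways of fitting the comparison, 3 gave any call at an adjusted p below 0.05. Leaving out each library in turn gave 0 transcripts higher and 0 to 1 lower, the 1 appearing without melatonin replicate 1. DESeq2 called 2 higher; one is ENSBTAT00000048711 and the other, outside the transcripts given by identifier, had an adjusted p of 0.00514. With control 2 and melatonin 3 left out together, 3 were higher and 1 lower, all with an adjusted p of 0.0485 in limma, and the correlation within groups exceeded that between groups by 0.0243. Each of these libraries correlated better with the opposite group than with its own, and the pair was chosen after the files were seen. A higher correlation within groups was therefore built in, and more calls were likely. Only 2 libraries per group remained, and the cause was not tested. With the replicate block, 0 transcripts passed, and 299 instead of 425 had an unadjusted p under 0.05. Deviations of same-numbered libraries from their group means correlated at -0.49, 0.27 and -0.21. Only melatonin replicate 2 correlated best with its own number, so these values showed no pairing by number. Control replicate 1 and melatonin replicate 3 deviated together most (0.58), and the deviations within a group are tied to each other. A weaker shared collection or day would therefore not show in this check. Without the adjustment, a p under 0.05 with at least a 2-fold change selected 26 higher and 92 lower, because that threshold is looser. DESeq2, edgeR, both pairs left out together, Spearman correlation, the 50 highest transcripts, the length trend, thinning, the omission of abundant transcripts and median-ratio detection were chosen after the files were seen. The remaining alternatives kept both counts at 0, and the 4 transcripts given by identifier kept their direction wherever they were tested. Their size depended on the setting: with a pseudocount of 0.1 the log2 fold change was 5.32 for ENSBTAT00000048711, -3.94 for ENSBTAT00000064571 and -4.71 for ENSBTAT00000064889. For ENSBTAT00000022919 it was 0.27 with quantile normalization only. Every other setting that tested it gave 0.73 (libraries scaled to the same sum) to 1.07 (median-ratio scaling). The planned gene list tests and the mitochondrial share were not run, because identifiers had no gene names. Array weights raised the transcripts at an unadjusted p under 0.05 to 1510, with 0 past the adjusted threshold.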

Other observations

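The split tests, the check of exchanged labels, the split by library totals, the fold changes by length decile and the share of fold change left after the length correction were chosen after the result was seen. The number of calls left after the length correction and the test of abundant transcripts were set down before their values were known, and the ranges over left-out libraries were added afterwards. The test of abundant transcripts replaced one by median-ratio scaling, which gave 43.3% lower. That scaling centres the values and so takes out a shift shared by most transcripts, whatever its origin. Centring does not fix the share lower: it was 63.9% in edgeR and 58.6% in DESeq2, which also centre.

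By number of calls, the strongest contrast among the 6 libraries did not follow the treatment labels. Of the 10 ways to split them into 3 and 3, the split of control replicates 1 and 3 and melatonin replicate 3 from the rest gave 193 transcripts past an adjusted limma p of 0.05 and 526 in edgeR. The treatment split gave 0 in both, against these highest other values. At an unadjusted limma p under 0.05 the treatment split gave 425 transcripts. Counting the treatment split itself, 3 of the 10 splits gave at least as many, and the highest other gave 2221. With 10 splits no share below 0.05 is possible. A split that calls many more transcripts than the treatment points to a structure of the libraries that their labels do not record. Control replicates 1 and 3 and melatonin replicate 3 were not a tight group, however. Control replicate 3 and melatonin replicate 3 correlated at r = 0.943, below the between-group mean of 0.955. They lay at opposite ends of the second principal component (-36.3 and 31.6). Control replicate 2 and melatonin replicates 1 and 2 correlated at 0.977 to 0.980.

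Depth is argued against as the source of that structure, since the split of the 3 libraries of highest total (control replicates 1 and 3 and melatonin replicate 1) from the rest gave 1 call in limma and 1 in edgeR. Thinning the counts to the lowest total left 190 calls, but with totals within 1.08-fold it changed little and decides nothing. A trend with transcript length may account for part of it. In the shortest length decile of transcripts (median 609 bases) the median deviation from the mean of the 6 libraries was -0.29, -0.21 and -0.24 on the log2 scale in control replicates 1 and 3 and melatonin replicate 3, against 0.20, 0.23 and 0.34 in control replicate 2 and melatonin replicates 1 and 2. Transcripts of middle length did not follow this split: in the decile with a median of 2044 bases the median deviation was 0.17 and 0.25 in control replicates 1 and 3 but -0.24 in melatonin replicate 3. With each library's length trend removed, 5 calls were left, as the median absolute log2 fold change of the 193 transcripts shrank from 1.40 to 1.22 and its median standard error grew from 0.25 to 0.27. Of that fold change 87.3% remained (bootstrap 95% interval 83.9% to 91.5%). Transcripts of the same 6 libraries are not independent, so that interval can be too narrow. The 193 transcripts were picked for large differences in this same split, so a large remainder is likely whatever the source. The 5 calls left met the outcome set down beforehand for a length trend. The values therefore do not settle how much of the differences the trend accounts for. Values point both ways on exchanged labels of control 2 and melatonin 3. Each was closer to the other 2 libraries of the opposite group than to those of its own, by 0.022 in r for either. With the labels exchanged, however, control replicate 3 would correlate less with its own group than with the other (difference of -0.00747 in r), which is within the SD of 0.0143 among the within-group values so formed. The share of the 10 highest transcripts was 17.7% in control 2 and 21.9% in melatonin 3. Summed FPKM was 776138 and 827937, so each library was on the side of its label. Both measures part the labelled groups without overlap, so every library lies on its label's side. The count-weighted length of control 2 (2172 bases) lay within the melatonin range (2128 to 2177), against 2235 and 2365 in control replicates 1 and 3. That of melatonin 3 (2128) was on the side of its label. With 3 libraries per group these measures do not settle which label is right. The exchange stays open, and under it the split with 193 limma calls would be the treatment split. An unrecorded batch or a difference between oocyte pools could give the same values, and no label bears on it.

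The lean towards lower values with melatonin (84.2% of transcripts at an unadjusted p under 0.05) was the other pattern weighed. The treatment split had 618 more transcripts wholly below than wholly above the other group. That was the largest excess in either direction among the 10 splits, and the highest other was 561. With 10 splits, however, no share below 0.05 is possible. The lean varied with transcript length: the median log2 fold change was 0.218 in the shortest length decile (0.103 to 0.376 without each library in turn), -0.24 in the decile with a median of 2044 bases and -0.14 in the longest (-0.21 to -0.07). Removing each library's length trend made the lean larger, with 25 higher and 481 lower (95.1% lower) and a median log2 fold change of -0.19. The removal kept each library's median and so cannot take out a shift of the medians. Whether a length trend accounts for part of the lean stays open. That the few most abundant transcripts take up more of each melatonin library may explain part of the lean. With the 10 highest left out and the rest rescaled it was 77.6%, the side set down beforehand as against this explanation. Without each library in turn that share was 55.4% to 85.4%. With the abundant transcripts kept it was 59.9% (without melatonin replicate 3) to 88.7% (without melatonin replicate 2). Their omission moved the share less than leaving out melatonin replicate 3 did. It therefore does not settle whether they explain a part. An effect of melatonin itself stays open and untested.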
